A study of Homo sapiens with 26 samples.

How the data were processed

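Human theca cell cultures were measured on Affymetrix HG-U133A and HG-U133B arrays, with the chip type per the file headers. The deposited values are 1 intensity per probe set and array on a linear scale. How the probes were summarised and normalized is not given in the sources used here. The values themselves show that each array had been scaled to the same mean, 150 after leaving out the lowest and highest 2% of probe sets. Experiment files of the scanner software were read only for the chip type and to code hybridization batches, chip lots and fluidics protocols as numbers. Groups and replicate numbers came from the labels, and the labels do not say what a replicate number marks. All 26 arrays were used, 13 of each type.

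Arrays of the 2 types were scaled and tested apart. Intensities were taken to log2(intensity + 32), which understates the change of dim genes, and the deposited scaling was kept. Array A held 22283 probe sets, of which 68 controls and 125 of genes that can mark a person (sex-linked genes, common deletions and highly polymorphic immune genes) were left out, and array B held 22645, of which 68 and 41 were left out. Probe sets under the 25th percentile of mean value were removed (log2 5.68 on array A and 5.96 on array B), which left 16567 and 16902. Gene names came from the platform annotation, updated through the RefSeq genes of assembly GRCh38.p14, whose coordinates only ordered the genes for the test of neighbouring genes. Of the tested probe sets, 14534, 768 and 1265 on array A had 1, several or no gene symbol, and 12116, 438 and 4348 on array B. Of those with 1 symbol, 14528 and 12100 matched a RefSeq gene, and probe sets with several symbols were not named.

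Linear models were fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with 1 estimate of the spread from all 13 arrays of a type. The 3 comparisons were tested two-sided, with Benjamini-Hochberg adjustment within an array type and comparison, at an adjusted p of 0.05. For 34 gene lists fixed before the data were examined, 1 probe set per gene (the one with the highest mean, from array A where both arrays had the gene) was tested. A list needed at least 5 tested genes. The tests were camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. No list reached that number with genes found only on array B, so a test of all listed genes on array B was added after seeing the data.

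The genes named follow a rule written before the data were examined. For each comparison these are, among genes that passed by their probe set with the highest mean and whose groups did not overlap, the 10 highest and 10 lowest changes on array A and the 4 highest and 4 lowest on array B, up to 4 members of smallest p in each list described, and CYP17A1, CYP11A1, STAR, LHCGR, HSD3B2, GATA6, CDKN1A and ABAT whatever their p. Another gene of that rule is not reported here.

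The correlation of valproate and PCOS changes was compared with 100 simulations without effects that kept the shared controls, and with the 4 controls split into pairs. Shared calls were counted in 100 such simulations as well, by the threshold and by taking as many probe sets by rank as were called in each direction. Other splits of the arrays, 35 or 100 of them, were counted for each comparison. Recovery was tested on simulated data with 200 changed probe sets per comparison. On array A 71% of 2-fold and 94% of 4-fold changes were recovered for valproate and 62% and 96% for PCOS, and on array B 22% and 94%, and 31% and 90%.

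The alternatives were pseudocounts of 1 and 100, quantile normalization, no filter and a filter at the 50th percentile, eBayes without a trend, a replicate block, only the 2 groups compared, 1 probe set per gene, and each array left out in turn. Median centring and the hybridization batch as a random block were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.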

Results

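Gene expression was measured in long-term cultures of human theca cells, the cells of the ovarian follicle wall that make androgens. There were 3 groups: untreated cells from normal ovaries (4 samples), normal cells treated with 500 uM valproate for 48 h (4 samples), and untreated cells from ovaries with polycystic ovary syndrome, PCOS (5 samples). Each group was measured on 2 Affymetrix arrays that carry mostly different probe sets, HG-U133A (array A) and HG-U133B (array B), giving 26 arrays in all. The labels do not say whether the samples of a group came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every comparison. Changes are differences of log2(intensity + 32) ± standard error, tested with limma and adjusted by Benjamini-Hochberg within each array type. Genes are ranked by 1 probe set each, the one with the highest mean, so other probe sets of a gene can lie further out.

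The valproate-treated arrays stood apart on the first principal component of array A and the untreated normal arrays on that of array B, while neither of the first 2 components of array A separated PCOS from untreated normal arrays. Some technical measures separated the groups too. The groups were hybridized in 4 batches, and each batch held samples of 1 group: batch 4 the untreated normal cells, batch 2 the valproate-treated cells, and batches 1 and 3 the PCOS cells, with PCOS replicate 5 alone in batch 3. The untreated normal arrays also came from their own chip lot and fluidics protocol. The ratio of 3' to 5' signal of the actin control ACTB, a measure of transcript length after labelling, was 0.855 ± 0.071 (SD, n = 4) in untreated normal, 1.12 ± 0.030 (n = 4) in valproate-treated and 1.34 ± 0.133 (n = 5) in PCOS samples on array A. On array B the same ratios were 0.853, 1.17 and 1.36, and untreated normal samples overlapped with neither of the other groups. Batch and group can therefore not be told apart in any of the 3 comparisons. Only the PCOS group spans 2 batches, and a fit with the batch as a random block stands beside each count below. Its batch correlation rests on PCOS replicate 5 against the other PCOS arrays. That 1 correlation is applied to all probe sets, so a call kept or lost under it does not show whether batch moved that gene. On array B the correlation was negative (-0.0617), which no batch variance can give. A negative value narrows the standard errors, so the higher array B counts under this block make no allowance for batch.

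**Figure D1:**
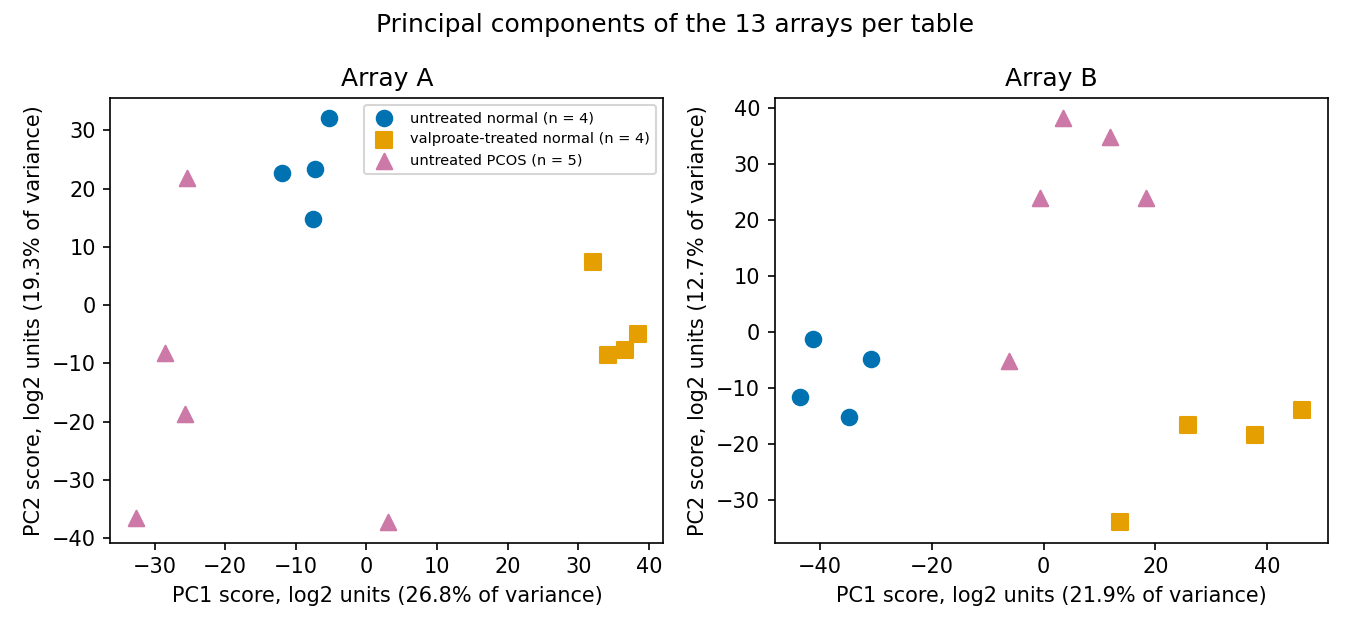
Scores on the first and second principal components (log2 units) for array A (left) and array B (right), 1 point per array, coloured by group. On array A the components held 26.8% and 19.3% of the variance and all 4 valproate-treated arrays scored above every other array on the first component, while the PCOS arrays were the most spread.

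Valproate, an anticonvulsant that also inhibits histone deacetylases, has been linked to PCOS-like features in its users, so treated and untreated normal theca cells, which were also processed apart, were compared. The gene with the highest increase on array A was IGFBP5, which binds insulin-like growth factors: it was 4.35-fold higher (log2 change 2.12 ± 0.41, adjusted p = 0.00537, n = 4 against 4). SELENOP, a selenium carrier (1.86 ± 0.30), KCNN4, a calcium-activated potassium channel (1.84 ± 0.21), and SV2A, a synaptic vesicle protein (1.53 ± 0.23), were also among the 10 highest. Lowest was PYGB, the brain form of glycogen phosphorylase, 6.21-fold lower (-2.63 ± 0.38, adjusted p = 0.000964). The mechanically gated channel PIEZO1 (-2.33 ± 0.20), the mTOR pathway inhibitor TSC2 (-2.10 ± 0.24) and the transcription elongation kinase CDK9 (-1.98 ± 0.20) were lower as well.

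The other genes among the 10 highest were HLA-F-AS1, ATP8B1, TMEM176A, PROCR, ITGA7 and SLC12A8, and the 10 reached up to 2.12. BTBD2, CLIC3, ARPC4, SLC10A3, PPP4C and ATP13A2 completed the 10 lowest, which lay between -2.63 and -1.98. Adjusted p ranged from 0.000156 to 0.00954 among the highest and from 2.99e-05 to 0.00863 among the lowest, and no array of one group overlapped with the other. Other probe sets did not always move alike: of 62 other probe sets of the named genes called here, 51 had the same direction, 20 of them called, and 2 were called in the opposite one. Over all genes with 2 or more called probe sets, 7 of 139 on array A and 9 of 48 on array B had calls in opposite directions. Other IGFBP5 probe sets gave 2.40 and 1.10, both called, and 0.73 and 0.43, not called. A PYGB probe set on array B was higher by 1.66 (adjusted p = 0.00316), and 2 CDK9 probe sets there gave 0.19 and -0.72, neither past the threshold. On array B the noncoding RNA MALAT1 rose 9.61-fold (3.26 ± 0.44, adjusted p = 0.000817). Of its 10 other probe sets, 5 were also called higher, and the rest, from -0.72 to 0.51, did not pass. RPL7AP9 (2.19), RAB4B (2.14) and RIDA (1.95) followed MALAT1. ZNF598, a ubiquitin ligase that senses stalled ribosomes, fell most (-2.99 ± 0.38, adjusted p = 0.000523), followed by TPGS1 (-2.45), ZMYND19 (-2.39) and ALDH16A1 (-2.36). Second probe sets of ZNF598 (0.65), TPGS1 (-0.07), RIDA (0.35) and ATP8B1 (0.01) did not pass.

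Of 20 glycolysis genes, 4 fell after valproate, 0 rose and 16 did not pass (5 fell adjusted over the list alone). The list stood below other genes by camera (adjusted p = 0.000372), or adjusted p = 0.590 with an estimated correlation. Aldolase ALDOA (-1.30 ± 0.13, adjusted p = 4.89e-05) and the phosphofructokinases PFKL (-1.24 ± 0.15) and PFKP (-0.94 ± 0.23) were lower, as was the isomerase GPI (-0.91 ± 0.25). A second ALDOA probe set on array A (-1.49) and another on array B (-1.40) were also called lower. The ACTB 3' to 5' ratio was 1.31-fold higher in the treated arrays of the same comparison. Of 23 genes of endoplasmic reticulum stress and heat shock, 5 fell, 0 rose and 18 did not pass (1 rose and 5 fell adjusted over the list alone). They included the chaperone CALR (-0.66 ± 0.18) and TRIB3, a target of the stress factor ATF4 (-1.18 ± 0.35), and the list's adjusted p was 0.0487 (adjusted p = 0.590 with an estimated correlation). Other CALR probe sets gave -0.05 and -0.27, neither past the threshold. Smooth muscle and myofibroblast genes had 2 of 12 lower, SMTN (-0.96 ± 0.21) and desmin, DES (-0.78 ± 0.19), with 0 higher and 10 not past (2 lower adjusted over the list alone). That list's adjusted p was 0.0487 (adjusted p = 0.677 with an estimated correlation), and both lists missed the threshold after quantile normalization and after centring arrays on their medians.

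Lists that did not stand apart as a whole still held single genes that changed. Among 23 genes of insulin and IGF signalling, 4 rose, 1 fell and 18 did not pass (5 and 2 adjusted over the list alone): FOXO1 (0.88 ± 0.15) and IGF1 (0.79 ± 0.18) rose and AKT1 fell (-0.77 ± 0.19). Of 21 retinoid genes, 3 rose, 0 fell and 18 did not pass (3 rose adjusted over the list alone), among them the receptors RARG (1.12 ± 0.23) and RARB (0.65 ± 0.20). Other RARG probe sets gave -0.22 and 0.30, neither past the threshold. RARB and LRAT (0.61 ± 0.17) were no longer called after median centring. Retinoid, WNT and GATA6 genes were reported in earlier PCOS theca work of the same group, possibly on these samples, so they are not independent evidence of direction. Of 24 WNT genes, 3 rose, 1 fell and 20 did not pass (4 and 1 adjusted over the list alone), with DKK3 higher (0.94 ± 0.20) and AXIN1 lower (-1.24 ± 0.27). The 4 other DKK3 probe sets, from -0.37 to 0.57, did not pass. Histone genes had 0 higher, 2 lower and 10 not past (2 lower adjusted over the list alone), H1-10 (-1.24 ± 0.26) and H2BC12 (-1.10 ± 0.29). Of 12 leukocyte and macrophage markers, 2 rose, 0 fell and 10 did not pass (2 rose adjusted over the list alone): CD163 (1.34 ± 0.22) and CD2 (0.57 ± 0.16), the latter not called after median centring. Beyond the 3 lists that passed, 31 lists did not (smallest adjusted p = 0.0761, genes of RNA quality and early response, of which 1 of 14 fell). On array B none of 21 lists passed (smallest adjusted p = 0.201, 0.517 with an estimated correlation).

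The androgen synthesis genes CYP17A1, CYP11A1, STAR and HSD3B2 did not pass the threshold after valproate. CYP17A1, which commits steroids to androgen synthesis, changed by 0.44 ± 0.37 (adjusted p = 0.464), CYP11A1 by 0.15 ± 0.26 (0.746), STAR by 0.04 ± 0.50 (0.965) and HSD3B2 by 0.30 ± 0.27 (0.485). Of 27 steroidogenesis genes, 1 rose, 0 fell and 26 did not pass (1 rose adjusted over the list alone): HSD17B6 (1.13 ± 0.26, adjusted p = 0.0149). ABAT, which degrades GABA and is inhibited by valproate, was higher by 0.74 ± 0.27 without passing (0.0802), and the cell cycle inhibitor CDKN1A changed by -0.27 ± 0.30 (0.577). The luteinizing hormone receptor LHCGR lay below the intensity filter.

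In all, 1983 of 16567 probe sets on array A changed (1237 higher, 746 lower), and 1355 of 16902 on array B (779 higher, 576 lower). The groups did not overlap for 25.6% of probe sets on array A, where chance gives 2.86%. The median change was 0.13 on array A and 0.14 on array B, and with the 50th percentile filter it was 0.06 and 0.09. Each change was tested against 0, not against that shift. After median centring, chosen after seeing the data, 381 were higher and 1522 lower on array A (62.4% higher in the deposited scaling) and 291 and 1129 on array B. Quantile normalization gave 657 and 849 on array A and 407 and 533 on array B. With the batch as a random block, also added later, the counts were 272 on array A and 2707 on array B, where the batch correlation was negative. Under that block the calls of IGFBP5, TMEM176A, SLC12A8 and ARPC4 among the 20 extreme genes of array A were lost, as were those of HSD17B6, PFKP, GPI, IGF1, AKT1, CD2 and every retinoid, WNT, histone, smooth muscle and stress gene named. Omitting single arrays moved these counts by over 1.5 times, with the lowest, 991 and 544, without valproate-treated replicate 3.

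**Figure D2:**
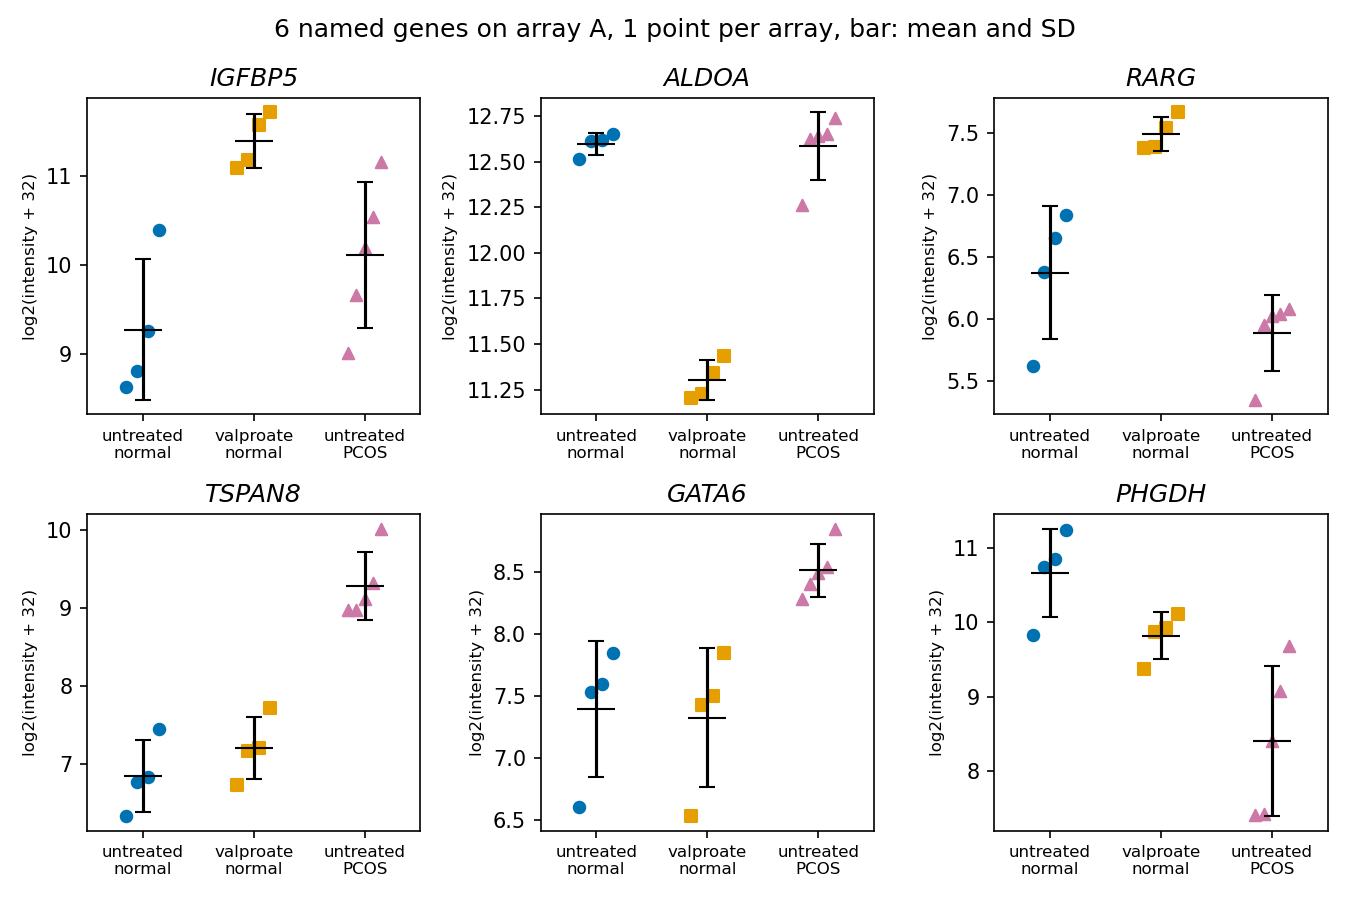
log2(intensity + 32) of 6 named genes on array A, 1 point per array, with bars for the group mean and SD (n = 4, 4 and 5). IGFBP5 and RARG are highest and ALDOA lowest in valproate-treated cells, TSPAN8 and GATA6 are highest and PHGDH lowest in PCOS cells.

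PCOS and normal theca cells were compared to find how theca cells of the syndrome differ in culture. The highest gene on array A in PCOS cells was TSPAN8, a membrane tetraspanin, at 5.41-fold (log2 change 2.43 ± 0.26, adjusted p = 0.000760, n = 5 against 4). RARRES1, a retinoic acid responder (1.70 ± 0.31), NDUFA13, a subunit of respiratory complex I (1.57 ± 0.23), and the RNA splicing proteins SNRPD3 (1.44 ± 0.17) and SNRNP35 (1.24 ± 0.21) were also higher. By these probe sets PHGDH, an enzyme of serine synthesis, was lowest, 4.81-fold lower (-2.27 ± 0.41, adjusted p = 0.00647), followed by the asparagine synthetase ASNS at 4.51-fold (-2.17 ± 0.44, adjusted p = 0.0120). The amino acid transporter subunits SLC3A2 (-1.71 ± 0.28) and SLC7A5 (-1.39 ± 0.29) and TRIB3 (-1.75 ± 0.33) were lower too.

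CKS2, HNRNPA2B1, LSM1, TNFSF10 and RPS27L completed the 10 highest (1.18 to 2.43, adjusted p 0.000760 to 0.0142). NIBAN1, CNN1, EXOC3, LOXL1 and PGAP6 completed the 10 lowest (-2.27 to -1.22, adjusted p 0.00138 to 0.0293). No array of one group overlapped with the other for any of these 20 genes. Probe sets outside this ranking reached further for some genes, with called values of 1.40 for UQCRB, 1.26 for DCN, -1.83 for LOXL2 and -3.20 for THBS1, while others of UQCRB (0.26) and LOXL2 (0.41) did not pass. Of 58 other probe sets of the called named genes 45 had the same direction, 10 of them called, and 0 were called in the opposite one (over all genes with 2 or more called probe sets, 1 of 73 on array A and 0 of 17 on array B had opposite calls). On array B PLPP7 was lowest (-2.13 ± 0.21, adjusted p = 0.000154), followed by CCDC167 (-2.00), STK11IP (-1.95) and TP53I13 (-1.92), and ZNF705G (1.55), RAD54L2, UBE2E2-DT (1.47) and CLIP1 (1.46) were highest.

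Of 28 mitochondrial respiratory chain genes, 9 rose in PCOS cells, 0 fell and 19 did not pass (10 rose adjusted over the list alone), led by COX7B (1.15 ± 0.18), UQCRB (1.01 ± 0.18) and COX6C (0.88 ± 0.16). The list stood above other genes by camera (adjusted p = 0.00226, or adjusted p = 0.817 with an estimated correlation). Of 26 cytosolic ribosomal proteins (adjusted p = 2.82e-05, or adjusted p = 0.817 with an estimated correlation), 4 rose, 0 fell and 22 did not pass (4 rose adjusted over the list alone): RPL11 (0.78 ± 0.15), RPS25 (0.63 ± 0.12), RPL22 (0.61 ± 0.17) and RPL37 (0.51 ± 0.13). On array B the probe sets of RPL11 (0.26), RPS25 (0.41) and RPL37 (4, from -1.29 to 0.25) did not pass. Smooth muscle and myofibroblast genes were lower, with 4 of 12 down, 0 up and 8 not past (6 down adjusted over the list alone): DES (adjusted p = 0.00685), calponin CNN1 (-1.62 ± 0.40), ACTG2 (-1.11 ± 0.28) and ACTA2 (-0.84 ± 0.22). The list's adjusted p was 0.00500 (adjusted p = 0.817 with an estimated correlation). The ACTB 3' to 5' ratio was 1.56-fold higher in the PCOS arrays of type A than in the normal ones.

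Steroidogenesis genes stood above other genes in PCOS cells, with adjusted p = 0.0334 (adjusted p = 0.817 with an estimated correlation). Of 27 tested, 4 rose, 0 fell and 23 did not pass, and 5 rose and 1 fell when adjusted over the list alone. The transcription factor GATA6 was 2.17-fold higher (1.12 ± 0.26, adjusted p = 0.0238), although its array B probe set gave 0.26 ± 0.32 (adjusted p = 0.692) and the call was lost without normal replicate 4. HSD17B6 (1.09 ± 0.25), CYB5A, which aids the lyase step of CYP17A1 (0.81 ± 0.20), and HSD17B4 (0.75 ± 0.19) rose. Higher values that did not pass were found for CYP11A1 (0.73 ± 0.25, adjusted p = 0.0989), HSD3B2 (0.69 ± 0.26, 0.132), STAR (0.93 ± 0.47, 0.266) and CYP17A1 (0.58 ± 0.36, 0.366). CDKN1A (-0.60 ± 0.28, 0.222) and ABAT (0.36 ± 0.25, 0.440) did not pass either. The list was lost after quantile normalization and after median centring.

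Interferon response and inflammatory cytokine genes were higher as lists (adjusted p = 0.000189 and 0.000298, or adjusted p = 0.859 and 0.817 with an estimated correlation), but none of their 27 and 23 members passed alone, 0 of them also when adjusted over each list alone. BST2 changed by 2.05 ± 0.65 (adjusted p = 0.0806), IFITM3 by 0.49 ± 0.14 (0.0520), CXCL6 by 1.81 ± 0.52 (0.0562) and CCL2 by 1.35 ± 0.48 (0.112). Matrix genes moved both ways, with 2 of 35 higher, 4 lower and 29 not past (4 and 5 adjusted over the list alone), DCN up (1.05 ± 0.24) and LOXL1 (-1.24 ± 0.28) and THBS1 (-1.29 ± 0.32) down. The other THBS1 probe sets ranged from -3.20 (adjusted p = 0.00346) to 0.22 (adjusted p = 0.666). In the stress list 1 rose, 3 fell and 19 did not pass (1 and 6 adjusted over the list alone), the mitochondrial chaperone HSPE1 up (0.86 ± 0.15) and TRIB3, ASNS and HERPUD1 (-0.79 ± 0.17) down. FOXO1 (0.79 ± 0.14) and FOXO3 (0.72 ± 0.18) rose and AKT1 fell (-0.92 ± 0.18) among 23 insulin and IGF genes, of which 20 did not pass (2 and 1 adjusted over the list alone). Of 12 leukocyte and macrophage markers, 9 granulosa and 9 endothelial markers, the only call was GJA1 of the granulosa list (0.56 ± 0.16, adjusted p = 0.0489), where 1 rose and 1 fell adjusted over the list alone. In all, 6 of the 34 lists passed, and the smallest adjusted p of the other 28 was 0.103. On array B none of 21 lists passed (smallest adjusted p = 0.541).

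On array A 896 probe sets differed between PCOS and normal cells (354 higher, 542 lower) and on array B 349 (127 higher, 222 lower). A fit of only these 2 groups gave 310 on array A and 157 on array B. In it, 17 of the 49 called named genes on array A lost their call. The median change was -0.03 on array A and 0.10 on array B. The groups did not overlap for 7.94% of probe sets on array A, against 1.59% by chance. Median centring gave 422 higher and 391 lower on array A (51.9% higher, against 39.5%) and 56 and 411 on array B (against 36.4% higher in the deposited scaling). The counts depended on single arrays: without normal replicate 4 there were 265 on array A and 144 on array B, and without PCOS replicate 1 there were 1713 and 644. With the batch as a random block they were 107 on array A and 995 on array B, where the batch correlation was negative. Under that block the calls of TSPAN8, NDUFA13, SNRPD3, SNRNP35, CKS2, HNRNPA2B1, RPS27L, SLC3A2, EXOC3, COX7B and HSPE1 stayed on array A. Those of all other called named genes there were lost, including PHGDH, ASNS, GATA6, HSD17B6, CYB5A and HSD17B4. As 1 correlation served all probe sets, a kept call does not clear a gene of batch effects.

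Valproate-treated normal cells were also set against PCOS cells, which were hybridized in other batches. ARPC4, a subunit of the actin-nucleating Arp2/3 complex, was 7.95-fold lower in treated normal cells (-2.99 ± 0.44, adjusted p = 0.000897, n = 4 against 5), although a second ARPC4 probe set gave -0.08 ± 0.28 (adjusted p = 0.860). VCAM1, a leukocyte adhesion molecule (-2.41 ± 0.56), the cytokine IL32 (-2.21 ± 0.35), TSPAN8 (-2.08 ± 0.26) and the chemokine CXCL1 (-2.05 ± 0.69) were lower as well. ASNS was 3.68-fold higher (1.88 ± 0.44, adjusted p = 0.0106), and ITGA7 (1.69 ± 0.20), INHBE (1.63 ± 0.35), CSTA (1.63 ± 0.22) and RARG (1.61 ± 0.22) followed.

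GASK1B, KIF5C, SV2A, CEACAM21 and ZNF3 completed the 10 highest on array A (1.48 to 1.88), and PIEZO1, CDK9, CLIC3, the fatty acid synthesis enzyme ACACA (-1.94 ± 0.27) and the NF-kB inhibitor NFKBIA (-1.87 ± 0.34) the 10 lowest (-2.99 to -1.87). On array B the extremes were RPL7AP9 (1.81), TTYH2 (1.76), BEX2 (1.69 ± 0.24, adjusted p = 0.00572) and SPMIP1 (1.67) above, and ZNF598 (-1.72), TMCO4 (-1.72), TNIP2 (-1.70) and RAVER1 (-1.68) below. Of these 8 only BEX2 kept its call whichever array was left out, and 6 (all but BEX2 and SPMIP1) lost it in a fit of only the 2 groups. On array A that fit ended the calls of CXCL1, IRF7 and IRF9. Of 43 other probe sets of the called named genes 34 had the same direction, 13 of them called, and 1 was called in the opposite one. Over all genes with 2 or more called probe sets, 41 of 301 on array A and 1 of 3 on array B had calls in opposite directions. GATA6 was lower on array A (-1.19 ± 0.26, adjusted p = 0.00790) and not past the threshold on array B (0.55 ± 0.32, 0.441). CYP17A1 (-0.14 ± 0.36, 0.799), CYP11A1 (-0.59 ± 0.25), STAR (-0.89 ± 0.47, 0.185), HSD3B2 (-0.39 ± 0.26, 0.287), CDKN1A (0.34 ± 0.28, 0.404) and ABAT (0.39 ± 0.25, 0.287) did not pass.

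The ACTB 3' to 5' ratio was 1.12 in treated normal and 1.34 in PCOS arrays of type A, and the 18S ribosomal RNA control had a mean of 5.07 intensity units in the former and 105 in the latter, with no overlap. Here 10 of 34 lists passed, and none did with an estimated correlation (smallest adjusted p = 0.532). Glycolysis genes were lower (adjusted p = 0.00128), with 3 of 20 down, 0 up and 17 not past (3 down adjusted over the list alone), among them ALDOA (-1.28 ± 0.12). TPI1 fell too (-0.52 ± 0.15), while another of its probe sets was higher by 0.64 (adjusted p = 0.0488). Inflammatory cytokines were lower (adjusted p = 0.00164), with 7 of 23 down, 0 up and 16 not past (7 down adjusted over the list alone), including LIF (-1.36 ± 0.33), CCL2 (-1.66 ± 0.48) and CXCL6 (-1.66 ± 0.52). Interferon genes (adjusted p = 0.00146) had 2 of 27 down, 0 up and 25 not past (0 adjusted over the list alone), IRF7 (-1.60 ± 0.49) and IRF9 (-0.68 ± 0.20). Without PCOS replicate 4 the values of IRF7 and CXCL1 shrank to -0.99 and -1.22, both still called. The respiratory chain (adjusted p = 0.0112) had 4 of 28 down, 0 up and 24 not past (4 down adjusted over the list alone), led by ATP5PO (-0.78 ± 0.13). Cholesterol synthesis and uptake (adjusted p = 0.0122), ribosomal proteins (0.0153), fatty acid synthesis (0.0196) and histones (0.0382) were lower with 1 of 23, 2 of 26, 2 of 15 and 1 of 12 members down and 0 up. Adjusted over the list alone, 0, 0, 6 and 1 were down, and 3 genes of fatty acid synthesis were up. Neuronal and synaptic genes were higher (adjusted p = 0.0334), with 8 of 25 up, 0 down and 17 not past (8 up adjusted over the list alone), among them SYT11 (1.02 ± 0.15), SCG2 (1.02 ± 0.19) and the growth cone protein GAP43 (0.98 ± 0.20). Leukocyte and macrophage markers were higher (adjusted p = 0.0382), with 3 of 12 up, 0 down and 9 not past (7 up adjusted over the list alone): CD2 (0.66 ± 0.16), CD163 (0.81 ± 0.21) and CD3E (0.65 ± 0.18), all 3 not called after median centring. After quantile normalization the cytokine and interferon lists still passed and the other 8 did not, and the histone list was also lost after median centring.

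Between these groups 3347 probe sets differed on array A (2431 higher in treated normal cells, 916 lower) and 208 on array B (98 higher, 110 lower). Median centring gave 642 higher and 2144 lower on array A (against 72.6% higher in the deposited scaling) and 57 and 119 on array B. Quantile normalization gave 1164 and 1137 on array A. The median change was 0.15 and 0.04. The groups did not overlap for 17.7% of probe sets on array A, against 1.59% by chance. With the batch as a random block the counts were 696 on array A and 661 on array B, where the batch correlation was negative. Under that block the calls of ASNS, INHBE, VCAM1, CXCL1, GATA6, TPI1, LIF, CCL2, CXCL6, IRF7, IRF9, CD2, CD3E and CD163 on array A were lost. Without valproate-treated replicate 3 the counts were 2071 and 59.

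The changes after valproate and in PCOS were correlated across probe sets, with Pearson r = 0.386 on array A (Spearman rho = 0.361) and 0.654 on array B (0.628). Probe sets are not independent replicates. Both changes are measured against the same untreated normal arrays, and with no effect at all a simulation gave r of 0.525 and 0.526. Effects of 1 change alone lower r, so the covariance is the measure to set against the simulation. The covariance was 0.0615 on array A, against a simulated 0.0249, a difference of 0.0366, and 0.151 on array B, against 0.0441, a difference of 0.107. Shuffling the arrays' deviations from their group means gave covariances up to 0.0575 and 0.0652, the former just below the observed value. With the 4 control arrays split between the 2 changes the covariance was 0.0382 ± 0.0060 (SD over 6 splits) and 0.108 ± 0.0072, and r was 0.211 and 0.393. On array A 100 probe sets were higher and 149 lower in both changes, and 7 moved in opposite directions. Independent lists would share 26.4, 24.4 and 56.4, which leaves out the shared controls. Simulated data without effects had almost no shared calls (0.01, 0.01 and 0 on average). When as many probe sets were taken by rank as were called, a test added after seeing the data, they shared 160, 163 and 2.69. Those ranked probe sets hold noise alone, in which the shared controls weigh more than among calls that include effects. The ranked counts therefore do not decide whether the overlap on array A comes from shared controls. On array B 82 were higher, 104 lower and 0 opposite, against 5.85, 7.57 and 14.6 for independent lists and 55.7, 73.3 and 0.38 (72, 88 and 3 at most) for simulated ranks. The simulations drew each probe set independently, so probe sets that vary together would widen these ranges. HSD17B6 and FOXO1 were higher and TRIB3 lower in both changes, though a second FOXO1 probe set gave 0.28 in PCOS (adjusted p = 0.718). PYGB was lower in both on array A, while its array B probe set was higher in both (1.66 and 1.07, adjusted p = 0.00316 and 0.0426). All 4 genes were chosen for mention after their values were seen.

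**Figure D3:**
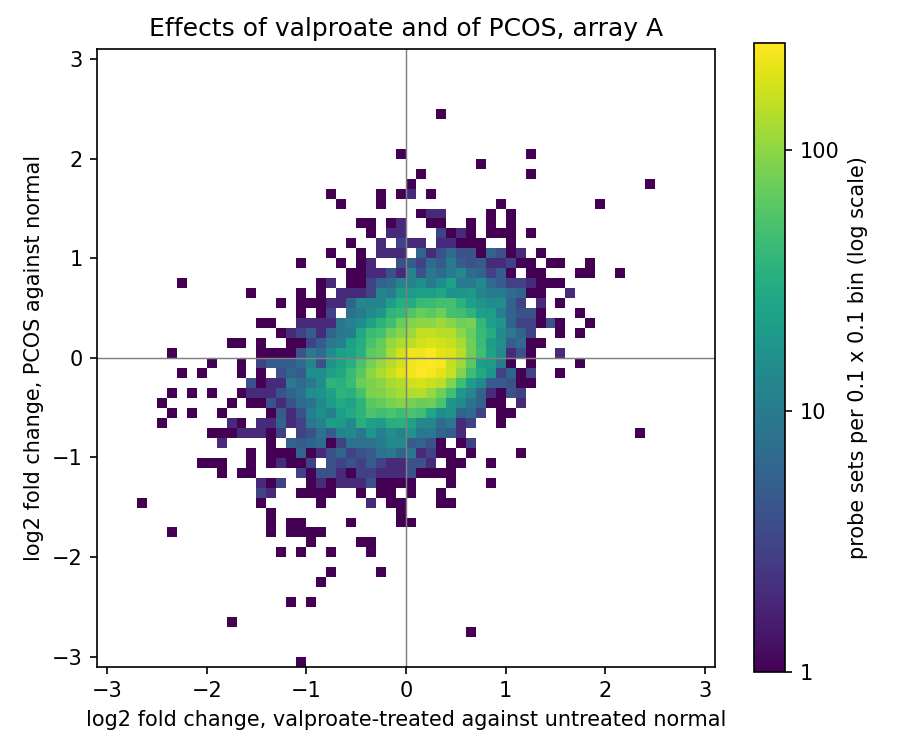
Changes in PCOS cells (vertical axis, log2 fold change) against changes after valproate (horizontal axis, log2 fold change) on array A, as counts of probe sets per bin of 0.1 by 0.1 on a log colour scale. Pearson r was 0.386 over 16567 probe sets, and both changes share the 4 untreated normal arrays.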

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

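Of the tests in this part, the one on batches shared between groups was chosen after the result was seen. Values below are the gap between the extreme sample and its nearest neighbour as a share of the group's range. Chance alone gives such a gap in about 1 of 20 groups.

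Among the genes named, 20 of 358 groups of samples had an extreme value, where 17.9 are expected by chance. In PCOS samples 1 sample stood low for CLIC3 (0.740), ALDOA (0.758), RARG (0.821), CNN1 (0.763), IFITM3 (0.765) and SMAD3 (0.711), and 1 stood high for LOXL1 (0.760) and IRF7 (0.779) on array A and CCDC167 (0.790) on array B. In valproate-treated samples 1 stood high for CDK9 (0.922), LRAT (0.850), LIF (0.854) and SMAD5 (0.884) on array A and TTYH2 (0.910) on array B, and 1 stood low for DES (0.912). In untreated normal samples 1 stood high for CDK9 (0.945), ATP13A2 (0.849) and WNT2 (0.873), and 1 stood low for ACACA (0.857) and HSD17B7 (0.850).

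Among the array measures, 8 of 60 groups had an extreme value, where 3 are expected by chance. In untreated normal samples the 18S ribosomal RNA control was high in 1 array of type A (0.954) and 1 of type B (0.931), at 2459 and 8440 intensity units against 117 and 619 for the nearest. Both carry replicate number 4, without which the PCOS count on array A was 265 in place of 896. That drop was not particular to this array: without normal replicate 3, with an 18S value of 26.5 on array A, the count was 335. The GAPDH 3' to 5' ratio was high in 1 array (0.928), the cre spike-in control low in 1 (0.867), and the mean rank correlation with the group's other arrays low in 1 of type A (0.893) and 1 of type B (0.834). Each of these values belongs to an array with replicate number 1. In valproate-treated samples cre was low in 1 array (0.839) and the Alu control high in 1 (0.835).

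Control signals outside the gene comparisons also differed between groups with no overlap. Against untreated normal arrays, PCOS arrays had higher bioB (4.95-fold on array A and 3.07-fold on array B), bioC (1.99-fold and 1.46-fold), bioD (1.31-fold) and cre (1.64-fold) on array A. Valproate-treated arrays had higher bioC (1.63-fold), bioD (1.49-fold), cre (1.45-fold) and Alu (1.10-fold) signal on array A, and lower 18S signal on array B (12.2 to 22.5 intensity units against 41.6 to 8440). Against PCOS arrays they were lower in 18S on array A (3.6 to 7.1 against 17.8 to 225) and array B (against 75.8 to 539), in bioB on both and in bioC on array A. The ACTB 3' to 5' ratio was 1.31-fold higher in valproate-treated and 1.56-fold higher in PCOS arrays of type A, and 1.37-fold and 1.59-fold higher in type B.

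The changed genes were weighed against chance and against processing. Of 35 splits of the 8 arrays, only the real one called as many as valproate did, 1 of 35 on each array type. It called 1983 on array A, 4 at most for other splits, and 1355 on array B, 1 at most. A share of 1 of 35 is the smallest this test can give, so a chance division of the arrays is unlikely but not excluded. For PCOS, 2 of 100 splits drawn from 126 called as many on each type, the real one and 1 other. That other split called more, 1267 against 896 and 381 against 349, so chance is not excluded. It set PCOS replicate 1 with the normal arrays, which points to a structure of the PCOS samples. For treated normal against PCOS cells 1 of 100 reached 3347 on array A (3325 at most) and 2 of 100 reached 208 on array B (302 at most, with PCOS replicate 5, alone in its batch, beside the treated arrays). No biological explanation was tested beyond the groups themselves, and 0 batches hold both groups, for valproate and for PCOS alike, so culture, extraction or labelling differences between groups processed apart cannot be told apart from treatment or disease. Fold changes of the same genes from different probe sets on array A and array B correlated weakly across 2968 genes (r = 0.205 for valproate, 0.220 for PCOS and 0.138 for treated normal against PCOS cells, shuffled genes reaching 0.057, 0.052 and 0.064), and of genes called on both arrays 25 of 36, 10 of 11 and 10 of 14 agreed in direction (25.2, 3.39 and 8.33 genes are expected to be called on both by chance), while the 100 probe sets present on both array types gave r of 0.883, 0.846 and 0.894, which leaves open how far hybridization differences of single probe sets could contribute.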

How the results depend on the processing

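No named gene that was called in the main fit or in the alternative reversed direction. Sign changes of genes called in neither were not counted. Of 184 alternative values of the main results, 125 stayed within 1.5 times (counts) or within the jackknife error (correlations). The rest follow, and median centring and the random batch block were chosen after seeing the data. Counts are for valproate, PCOS, and treated normal against PCOS cells. Counting genes gave 1151, 402 and 1923 on array A and 828, 208 and 123 on array B, as fewer features were tested. A fit of only the 2 groups gave 3421 (valproate) and 310 (PCOS) on array A and 157 (PCOS) and 69 (treated against PCOS) on array B. The 50th percentile filter gave 2223 for treated against PCOS on array A, and quantile normalization 218 for PCOS on array B. The random batch block gave 272, 107 and 696 on array A (consensus correlation 0.142) and 2707, 995 and 661 on array B (-0.0617). Under it, 22 of 63, 11 of 49 and 27 of 46 called named genes on array A stayed called. A batch block within groups was not run, since no batch held more than 1 group. The negative correlation narrowed the standard errors on array B, so the higher counts there make no allowance for batch. The cause was not tested for the other fits above, apart from the gene counts.

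Replicate numbers did not pair the samples: same-numbered untreated and treated normal arrays correlated at -0.111 to -0.022 on array A and -0.068 to 0.035 on array B, and 0 of 4 correlated best with their own number. Each untreated array correlated best with a different treated array of another number, and the matches were the same on both array types. These correlations were 0.186 to 0.274 on array A and 0.061 to 0.102 on array B. Treated and untreated samples may therefore be paired in a way that the labels do not give, which the fit without pairs ignores. The replicate block gave 211 for PCOS and 339 for treated against PCOS on array B, a correlation of effects of 0.603 there, and otherwise stayed within 1.5 times. Number 5 occurs only among PCOS arrays, so this block in effect leaves out PCOS replicate 5, without which the correlation was also 0.603. It matches arrays by number, including normal with PCOS arrays, so it is no test of pairing.

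Leaving out 1 array gave 991 to 2582 (valproate), 265 to 1713 (PCOS) and 1909 to 4418 (treated against PCOS) on array A, and 544 to 1625, 114 to 644 and 59 to 445 on array B. Correlation of effects ranged from 0.3003 to 0.441 on array A and 0.603 to 0.683 on array B. The arrays that moved a count over 1.5 times were, for valproate on array A, normal replicates 2 (1287), 3 (1038) and 4 (1052) and treated replicates 1 (1068), 3 (991) and 4 (1100). For PCOS they were normal replicates 2 (591), 3 (335) and 4 (265) and PCOS replicates 1 (1713), 2 (468) and 3 (596). For treated against PCOS they were treated replicates 1 (2193), 3 (2071) and 4 (1909). On array B they were, for valproate, normal replicates 1 (788) and 2 (752) and treated replicates 1 (667), 3 (544) and 4 (849). For PCOS they were normal replicates 1 (227), 2 (114), 3 (123) and 4 (144), PCOS replicates 1 (644), 2 (133) and 3 (193) and treated replicate 4 (215). For treated against PCOS they were PCOS replicates 1 (370), 2 (78), 3 (81), 4 (127) and 5 (445) and treated replicates 1 (63), 2 (95), 3 (59) and 4 (73). Of called named genes, 28 of 63, 26 of 49 and 11 of 46 on array A, and 0, 2 and 7 of 8 on array B, lost the call in at least 1 such fit. Signal over background limits dim genes: probe sets below the filter, such as LHCGR (log2 5.44), were not tested.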

Other observations

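The test on batches shared with untreated normal arrays was chosen after the result was seen.

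TGF-beta, BMP and activin signalling genes moved both ways between treated normal and PCOS cells: of 32 tested on array A, 6 were higher in treated cells, 2 lower and 24 not past by limma (6 and 2 adjusted over the list alone). The receptors TGFBR1 (0.90 ± 0.19, adjusted p = 0.00544) and BMPR2 (0.61 ± 0.14, 0.00910) and the transducer SMAD5 (0.73 ± 0.20, 0.0216) were higher, and SMAD3 was lower (-0.89 ± 0.14, 0.00155). Other probe sets did not pass for TGFBR1 (0.20 and -0.64) and SMAD5 (0.06 to 0.69), while 1 of 3 did for SMAD3 (-0.78) and 1 of 4 for BMPR2 (0.69). BMPR2 and SMAD5 were no longer called after median centring or with the batch as a random block. In PCOS cells TGFBR1 was the 1 member called, lower by -0.88 ± 0.19 (adjusted p = 0.0146), with 31 not past (1 lower adjusted over the list alone), a call lost with the batch block and not shared by its array B probe sets (-0.41 and 0.68). The list leaned lower in PCOS by fry (adjusted p = 0.000894) but did not stand apart from other genes by camera (adjusted p = 0.103, or adjusted p = 0.817 with an estimated correlation).

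Of 21 retinoid genes, 4 were higher and 4 lower in treated normal than in PCOS cells, with 13 not past (4 and 4 adjusted over the list alone). RARG (1.61 ± 0.22, adjusted p = 0.000675) and the transglutaminase TGM2 (0.93 ± 0.21, 0.00863) were higher, and RARRES1 (-1.79 ± 0.31, 0.00242) and the retinal reductase DHRS3 (-1.06 ± 0.21, 0.00478) lower, of which only TGM2 was lost with the batch block. The list did not stand apart by camera (adjusted p = 0.902), and it is not independent evidence, for the reason given above.

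A hypothesis was tested that the shared direction of valproate and PCOS changes comes from the untreated normal arrays alone. With the controls split into pairs the covariance stayed above 0. It was 0.0382 ± 0.0060 (SD over 6 splits) on array A and 0.108 ± 0.0072 on array B. The splits reuse the same control arrays, so this SD is not a sampling error and the splits alone decide nothing. On array A chance values of the shared controls remain open. There the covariance of 0.0615 lay above the simulated 0.0249 but barely passed the largest of 100 shuffled values, 0.0575. The simulated r of 0.525 does not bear on this, since effects of 1 change alone lower r. On array B the covariance of 0.151 lay above the shuffled maximum of 0.0652. That argues against chance values of the shared controls as the whole source on array B. Separate processing of the untreated normal arrays cannot be told apart from a shared change, since 0 batches on array A and 0 on array B hold untreated normal arrays with another group. A biological resemblance of the 2 states therefore remains open, as untested.

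A further hypothesis was that genes lower after valproate follow the regional base composition of the genome, so that neighbouring genes would move together. Fold changes of genes 10 places apart along a chromosome correlated at r = 0.0715 on array A (shuffled genes reached 0.0315) and 0.0245 on array B (0.0334). Single untreated and treated normal arrays, against the others of their group, gave -0.009 to 0.027 on array A and up to 0.031 on array B, and single PCOS arrays, outside this comparison, reached 0.133 and 0.080. No single array of this comparison reached the 0.0715 of array A. The value on array B lay within its shuffled range, so the hypothesis stays undecided. Base composition itself was not analysed here.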
